A study of Homo sapiens with 25 samples.

How the data were processed

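HL-60 cells were grown in medium with 15% serum and given 1.25% DMSO or 1e-07 M ATRA, per the labels. RNA was taken from 40000000 cells at each time and 8 µg of it was hybridised to an Affymetrix human U95 expression array (set A, version 2). The deposited values are probe set intensity on a linear scale, which the authors computed with MAS5, whose version and target value are not given in the sources used here. The table held 12558 probe sets on 25 arrays and 0 control probe sets. The 2% trimmed mean of every array lay between 1484 and 1489.9, within the tolerance of 10% set for using the values without further scaling. Detection calls and image data were not used here. The design text speaks of 24 arrays, 12 for each course, and the series holds 25, which the labels divide into 12 for each course and 1 at 0 h. For the samples titled 18 h the descriptions give 16 h, and the titles were followed.

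The constant c = 119.8, the 25th percentile of all values, was added to each signal before log2 was taken, so log2 changes and folds are those of signal plus c. Means and SDs of levels are of the signals themselves. Probe sets whose mean log2 value over the 25 arrays was under the 40th percentile were left out, which removed 5023 and kept 7535. Symbols came from the platform table and were matched to current gene names: 10943 probe sets had 1 gene, 545 had several and 1070 had none, and the last 2 kinds were tested but not named. The 7535 tested probe sets covered 5469 genes, 937 of them more than once, and a gene was read from its probe set with the highest mean.

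The comparisons, the lists, the threshold and the alternatives were chosen before the data were examined, except where said otherwise. Each course was divided into 4 windows of 3 arrays. Models were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), with 1 mean per treatment and window and 1 for the 0 h array, which left 16 residual degrees of freedom. Contrasts were the late against the early window of each course, the difference of these changes, ATRA against DMSO in each window, and the early and late windows against 0 h. A further limma model compared the 24 treated arrays with the time as a block. Tests were two-sided, and a probe set passed at a Benjamini-Hochberg adjusted p under 0.05 over the 7535 tested. Standard errors are those of the fit. The 0 h group had 1 array, which was assumed to vary like the windows. The ATRA and DMSO changes from 0 h share that array, so their overlap was not counted.

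A total of 32 lists of genes with known roles in granulocytes, growth and metabolism, with 775 entries of which 653 had a probe set, were tested with camera in limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. The same test was run with an estimated correlation, and members past the threshold were counted with p adjusted over all probe sets and over the list alone. Lists not mentioned were tested but are not described. The genes named were, for each comparison, among the 10 largest rises and 10 largest falls past the threshold whose arrays did not overlap between the groups (with 3 against 3, chance gives this in 10% of probe sets), up to 4 members of a list described, and a fixed set of markers of maturation reported whatever their result. For the 12 matched times the condition was the same direction at 10 or more. Genes given with opposite changes in the courses were chosen after their values were seen.

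Distances between whole profiles were root mean square log2 differences over the 7535 probe sets. They were correlated with log2 hours by Pearson's r and Spearman's rho, with two-sided permutation tests of 100000 resamples, whose smallest possible p is 1e-05, adjusted over 3 relations. The distances of late windows were compared by an exact permutation test, two-sided. Alternatives were a smaller constant or a floor at c, quantile normalization or centring on the median, no filter or a filter at the 60th percentile, eBayes with trend and robust, only the arrays of the comparison, each array left out in turn, a spline of time with 3 degrees of freedom, other windows, blocks and baselines, other probe sets of a gene, the mean of all its probe sets and the fry test. Leaving out the ATRA 7 d and DMSO 3 d arrays, and contrasts of 12-24 h with the early and late windows within each course, were chosen after seeing the data.

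The tests were tested on simulated data with 200 changed probe sets, independent normal noise of the spread within windows and no other effect of time. Far more probe sets passed in the real courses, so the shares found need not hold there. For the 12 times the added difference was constant. In the real data a difference that varies over time counts as error, so the shares for the 12 times may be too high. A log2 change of 1 was found in 56.5% of cases in the ATRA course, 48.6% in the DMSO course, 18.1% for the difference of the changes, 14.0% to 19.0% against 0 h and 91.8% over the 12 times. A log2 change of 2 was found in 87.5%, 93.0%, 62.7%, 66.7% to 77.9% and 100% of cases. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.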

Results

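Transcript levels were measured in HL-60, a human promyelocytic leukemia cell line that matures along the granulocyte line when given all-trans retinoic acid (ATRA) or dimethyl sulfoxide (DMSO). The series held 25 arrays. There was 1 array of undifferentiated cells at 0 h, 12 arrays of cells given 1e-07 M ATRA and 12 of cells given 1.25% DMSO. Both courses were sampled at 2, 4, 8, 12 and 18 h and at 1, 2, 3, 4, 5, 6 and 7 d, with 1 array at each time. Each course was read as 4 windows of 3 neighbouring arrays, 2-8 h, 12-24 h, 2-4 d and 5-7 d, and every SD below is over the 3 times of a window. These neighbouring times stood in for replicates, so the p-values measure only the spread between these samples. No untreated course was among the samples, so within a course the effect of the treatment and that of time in culture were not separable. The labels name a stationary state at day 6, inside the last window, and its part in the late changes was not tested. Signals were given for 12558 probe sets, of which 7535 passed the filter on low values. The median signal of an array lay between 338 and 497, and the number of arrays limited the precision. The ATRA 7 d array had the lowest mean correlation with the others of all 25 arrays, at 0.889.

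The labels say that maturation was followed by morphology, nitroblue tetrazolium reduction, phagocytosis and surface CD11b. The first question was which transcripts changed between the first hours and the late days of ATRA. The adhesion molecule CADM1 rose from a mean signal of 88.9 ± 103 at 2-8 h to 9517 ± 3520 at 5-7 d (SD, n = 3 each), a log2 change of 5.55 ± 0.50 (SE, adjusted p = 7.85e-07). CEACAM1, an adhesion receptor of granulocytes, rose 31.8-fold from 400 ± 44.8 to 16620 ± 3440 (adjusted p = 5.15e-07). The actin-binding protein PALLD rose 21.2-fold (adjusted p = 2.18e-06), the lysosomal sulfatase SGSH 17.2-fold (adjusted p = 4.95e-06) and properdin, encoded by CFP, 10.5-fold (adjusted p = 2.18e-06). ITGAM, which encodes CD11b, rose 8.37-fold, from 638 ± 243 to 6181 ± 1780 (log2 change 3.07 ± 0.45, adjusted p = 8.34e-05). Its partner chain ITGB2 rose 5.06-fold (adjusted p = 1.9e-05), and the lysosomal fucosidase FUCA1 7.03-fold (adjusted p = 5.52e-06).

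Other transcripts fell with ATRA. IGLL1, a light chain of the pre-B receptor, went from 12010 ± 478 to 162 ± 180 and fell by 5.61 ± 0.70 on the log2 scale (adjusted p = 1.46e-05). The neutrophil serine proteases PRTN3 and ELANE fell, with log2 changes of -3.91 ± 0.74 (adjusted p = 0.000784) and -3.65 ± 0.56 (adjusted p = 0.000118), and the related CTSG fell by 2.30 (adjusted p = 4.45e-05). MPO, the myeloperoxidase stored in the same azurophil granules, was at 94760 ± 8240 early and 103400 ± 18400 late, which was no change past the threshold (log2 0.11, adjusted p = 0.842). Of 9 azurophil granule genes 4 fell, against 5 down and 2 up when adjusted over the list alone (camera adjusted p = 0.00739, adjusted p = 0.232 with an estimated correlation). GAL, ZBTB16, LGALS1 and the intermediate filament gene VIM fell, with log2 changes of -3.48, -2.62, -2.44 and -2.87 (adjusted p = 6.74e-05, 7.32e-06, 0.0023 and 1.08e-05). MYC fell by 1.84 ± 0.24, from 11450 ± 2130 to 3101 ± 525 (adjusted p = 2.1e-05).

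Degradative and receptor genes rose in the ATRA course. Of 28 tested lysosome genes 21 rose, 2 fell and 5 did not pass, and 22 rose and 2 fell when adjusted over the list alone (camera adjusted p = 2.15e-11). This group was past the threshold also with an estimated correlation, at adjusted p = 0.0397. Among its members, the cholesterol carrier NPC2 rose 5.66-fold (adjusted p = 7.28e-06) and the acid lipase LIPA fell by 2.02 (adjusted p = 0.000117). Of 11 phagocytic and Fc receptor genes 6 rose, 6 also when adjusted over the list alone, among them the signalling adaptors TYROBP, by 4.44-fold, and FCER1G, by 4.13-fold (adjusted p = 4.36e-06 and 3.61e-05). The group passed camera at adjusted p = 0.000657, but with an estimated correlation it was at adjusted p = 0.232 and with the 60th percentile filter at 0.054. Of 24 interferon response genes 7 rose, 12 when adjusted over the list alone, with IFITM1 up 4.24-fold (camera adjusted p = 0.000657, adjusted p = 0.232 with an estimated correlation). Eicosanoid synthesis had 5 of 11 genes up, 6 when adjusted over the list alone, including ALOX5, the lipoxygenase of leukotriene synthesis, by 3.88-fold and TBXAS1 by 3.18-fold. Camera gave this group adjusted p = 0.0201, with 0.232 under an estimated correlation and 0.108 without the ATRA 2 h array, and a weak further probe set of ALOX5 showed no change (adjusted p = 0.881).

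Several groups of growth genes fell in the ATRA course. In the group of MYC targets and ribosome biogenesis 14 of 16 genes fell, 15 when adjusted over the list alone, with ODC1 and NME1 at log2 changes of -1.86 and -1.81 (camera adjusted p = 1.17e-09, adjusted p = 0.138 with an estimated correlation). DNA replication genes fell in 15 of 37 cases, 23 when adjusted over the list alone, among them MCM6 and POLD2 at log2 changes of -1.10 and -1.24 (camera adjusted p = 9.24e-08, adjusted p = 0.265 with an estimated correlation). Of 32 mitosis genes 7 fell and 1 rose, the same counts when adjusted over the list alone, with PTTG1 and CKS2 among the falls (camera adjusted p = 0.000657, adjusted p = 0.362 with an estimated correlation). Chaperones fell in 8 of 20 cases, against 10 down and 1 up when adjusted over the list alone, with HSPE1 at -1.15 (camera adjusted p = 9.9e-06, adjusted p = 0.232 with an estimated correlation). In the ER stress and amino acid response 8 of 17 genes fell, 9 when adjusted over the list alone, among them the chaperone CALR and the amino acid carrier SLC7A5 (camera adjusted p = 4.76e-05, adjusted p = 0.138 with an estimated correlation). Cytosolic ribosomal proteins moved the other way, with 2 of 45 up, 0 when adjusted over the list alone in limma, 3 at an unadjusted p under 0.05, and a median of 0.23 (camera adjusted p = 0.00543). They did not pass with an estimated correlation (adjusted p = 0.703), with quantile normalization (median 0.08, adjusted p = 0.161) or without the ATRA 5 d array (median 0.13, adjusted p = 0.141).

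The list of retinoid targets did not pass camera in the ATRA course (adjusted p = 0.0696), with 3 of 12 genes up and 1 down. DHRS3, a retinal reductase, rose 5.57-fold (adjusted p = 7.28e-06) and CD38 rose 3.42-fold, from 364 ± 368 to 1298 ± 359 (adjusted p = 0.00182). The granulocyte transcription factor CEBPE fell by 1.19 ± 0.29 (adjusted p = 0.00653), and without the ATRA 7 d array its adjusted p was 0.054. CYP26A1, the retinoic acid hydroxylase, and the oxidase subunit CYBB did not pass (log2 0.63 and 0.75, adjusted p = 0.251 and 0.247), though a weak further probe set of CYP26A1 passed (log2 1.51, adjusted p = 0.00465). In all, 1462 of 7535 probe sets passed the false discovery threshold in the ATRA course, 788 up and 674 down, and 730 of them changed at least 2-fold. The count was 966 without the ATRA 7 d array.

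**Figure D1:**
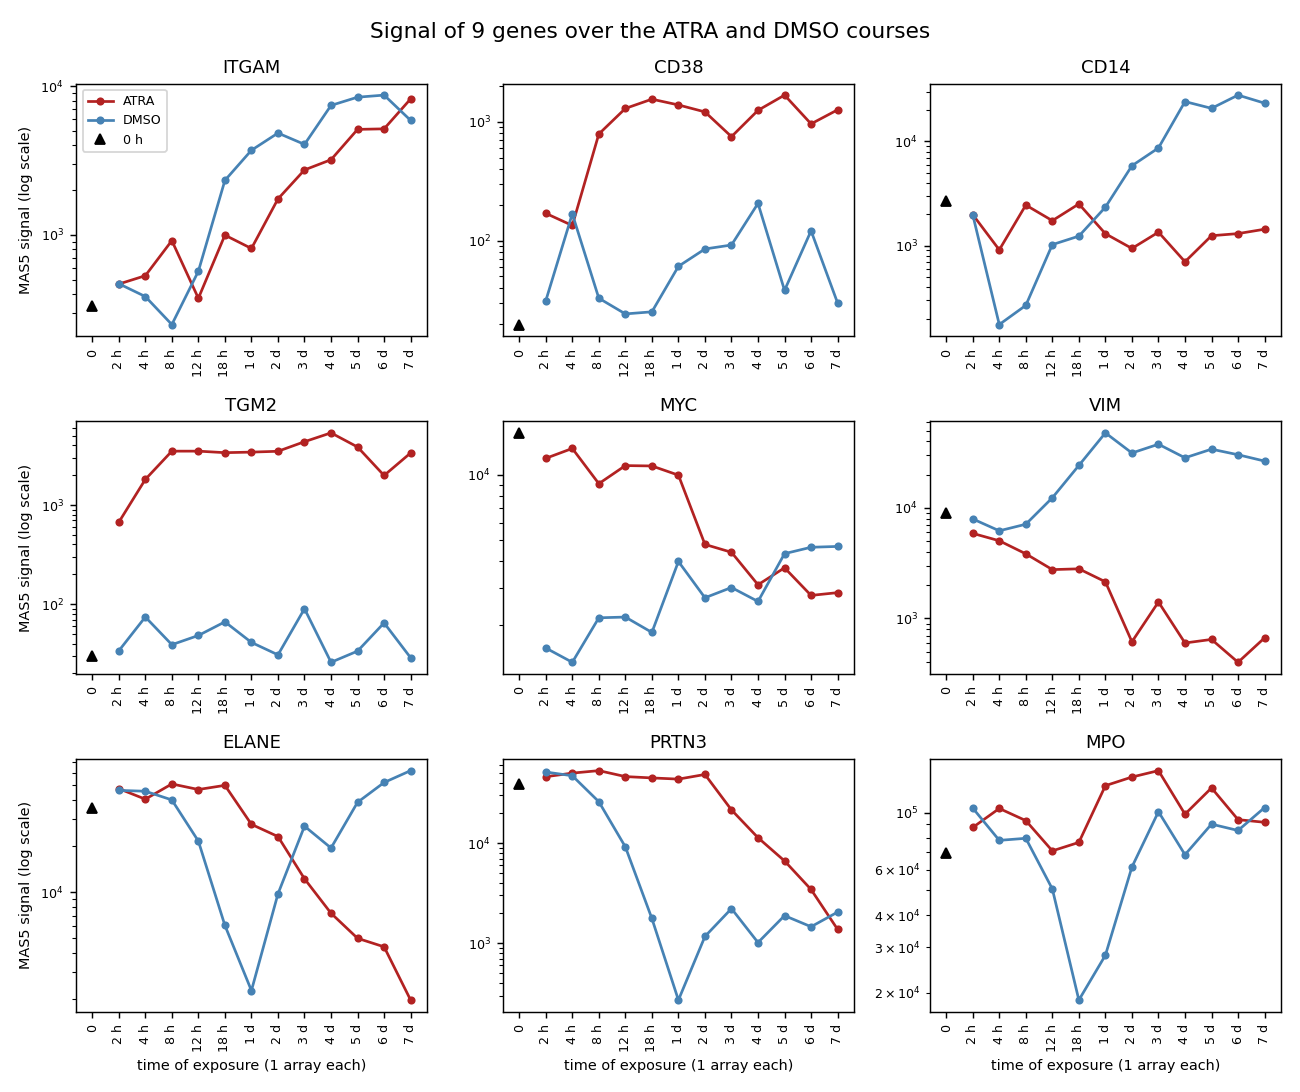
MAS5 signal of 9 genes on a log scale against time of exposure, with 1 array per point, ATRA in red, DMSO in blue and the 0 h array as a triangle. In the DMSO course ELANE went from 35429 at 0 h to 2284 at 1 d and 61891 at 7 d.

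The same question was asked of DMSO. The lipopolysaccharide receptor CD14 rose 38.5-fold, from 807 ± 1020 at 2-8 h to 23970 ± 3570 at 5-7 d (log2 change 5.27 ± 0.56, adjusted p = 3.28e-06). SGSH rose 16.5-fold, ITGAM 16.1-fold, the pattern receptor TLR2 9.25-fold, the inhibitory receptor LILRB3 8.65-fold, CDC42EP3 8.56-fold and PLXNC1 8.00-fold (adjusted p from 4.19e-07 to 1.03e-05). ITGAM went from 368 ± 111 to 7696 ± 1560. IGLL1 fell from 10910 ± 4670 to 217 ± 124 (adjusted p = 4.54e-05). GAL and PRTN3 fell, with log2 changes of -4.68 ± 0.50 and -4.39 ± 0.74 (adjusted p = 3.28e-06 and 0.000253), as did ITM2A and MATK at -2.93 and -2.50 (adjusted p = 1.89e-05 and 0.000108). ELANE and MPO were close to their early levels at 5-7 d (log2 0.19 and 0.11, adjusted p = 0.851 and 0.839), and so were CD38 and CEBPE (adjusted p = 0.915 and 0.66). CYP26A1 did not pass (adjusted p = 0.425). CYBB rose 2.80-fold (adjusted p = 0.0153), with adjusted p = 0.114, 0.0548 and 0.0628 without the DMSO 8 h, 5 d or 6 d array and 0.0509 from the arrays of the comparison alone. MYC rose from 1696 ± 425 to 4527 ± 189 (log2 1.38 ± 0.24, adjusted p = 0.000329). With the 0 h array counted among the early ones its change was 0.59 (adjusted p = 0.422), and 1 of its 3 further probe sets did not pass (adjusted p = 0.271).

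Receptor, adhesion, cytokine, transcription factor and lysosome lists each had from 5 to 12 members that rose with DMSO. Of 11 phagocytic and Fc receptor genes 8 rose, 9 when adjusted over the list alone (median log2 1.97, camera adjusted p = 2.13e-07). Leukocyte adhesion molecules rose in 7 of 13 cases, against 7 up and 1 down when adjusted over the list alone, with ITGAX up 4.95-fold and ITGB2 4.10-fold (camera adjusted p = 0.000325). Of 24 myeloid transcription factors 11 rose, 13 when adjusted over the list alone, among them CEBPD by 6.67-fold, GFI1 by 4.07-fold and CEBPB by 3.84-fold (camera adjusted p = 3.12e-05). This may in part be a return from lower levels at 2-8 h, a reading that rests on the 1 array at 0 h. At 0 h CEBPD was at 6376 and GFI1 at 10560, against 10330 and 11840 at 5-7 d. From 0 h to 5-7 d 1 of the 24 rose and 1 fell (camera adjusted p = 0.229), in a comparison that found 19% of simulated log2 changes of 1. Cytokines and NF-kB targets rose in 8 of 16 cases and fell in 1, with 10 up and 1 down when adjusted over the list alone, including CCL2, by 6.65-fold, and IL1B, by 3.03-fold (camera adjusted p = 0.000104), where CCL2 had been at 5983 at 0 h and reached 7145. A further probe set of CCL2 did not pass (adjusted p = 0.179). Of 9 chemoattractant receptors 5 rose, 5 when adjusted over the list alone, among them the leukotriene receptor LTB4R (camera adjusted p = 0.00493). Of 28 lysosome genes 12 rose, 14 when adjusted over the list alone, with CTSD up 3.12-fold (camera adjusted p = 1.27e-05). Each of these 6 groups was at adjusted p = 0.0788 with an estimated correlation. Single genes that rose included S100A9 by 6.51-fold, S100A8 by 4.05-fold, TNFRSF1B by 5.20-fold and ALOX5 by 4.66-fold, the last with a weak further probe set that did not pass (adjusted p = 0.201).

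Energy and division genes fell with DMSO. Of 37 oxidative phosphorylation genes 26 fell, 30 when adjusted over the list alone, with CYCS and ATP5MC3 at log2 changes of -1.55 and -1.49 (median fell by 0.78, camera adjusted p = 2.66e-13). Mitosis genes fell in 20 of 32 cases, 23 when adjusted over the list alone, among them AURKA, CKS1B and CCNB1 at -1.68, -1.49 and -1.34 (camera adjusted p = 1.29e-11). Chaperones fell in 13 of 20 cases, 13 when adjusted over the list alone, with HSPE1 at -1.30 and HSPD1 at -1.28 (camera adjusted p = 1.08e-07). These 3 groups were also at adjusted p = 0.0788 with an estimated correlation. DNA replication genes fell in 24 of 37 cases, 26 when adjusted over the list alone, with MCM4 at -1.64 (camera adjusted p = 2.84e-10, adjusted p = 0.162 with an estimated correlation). Of 16 MYC targets and ribosome biogenesis genes 7 fell and 1 rose, with 8 down and 1 up when adjusted over the list alone (camera adjusted p = 0.00281, adjusted p = 0.318 with an estimated correlation and 0.0648 without the DMSO 2 h array). Over all probe sets 1728 passed, 904 up and 824 down, and 798 changed at least 2-fold. Centring every array on its median moved the median log2 change of all probe sets by -0.141 and the counts to 687 up and 1124 down, and with quantile normalization they were 795 and 945.

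Markers of other blood lineages were tested beside these groups. Of 7 erythroid and megakaryocyte markers 0 passed in limma with ATRA and 0 with DMSO, where 1 and 0 had an unadjusted p under 0.05. Of 13 lymphoid markers 0 passed with ATRA, 2 at an unadjusted p under 0.05, and 3 with DMSO, 2 up and 1 down. Of 4 monocyte and macrophage markers 1 rose in each course, and the 1 with DMSO was CD14, given above. Most markers of that list had no probe set past the filter, so these counts say little about the lineage. Of 6 eosinophil, basophil and mast cell markers 3 fell and 1 rose with ATRA and 1 fell with DMSO, the same counts when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.26 and 0.198). Between treatments at 5-7 d, 1 of the 4 monocyte and macrophage markers was higher with ATRA and 1 lower, 2 and 2 when adjusted over the list alone, and 1 of the 6 eosinophil, basophil and mast cell markers was higher and 2 lower, the same when adjusted over the list alone (camera adjusted p = 0.698 and 0.652).

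**Figure D2:**
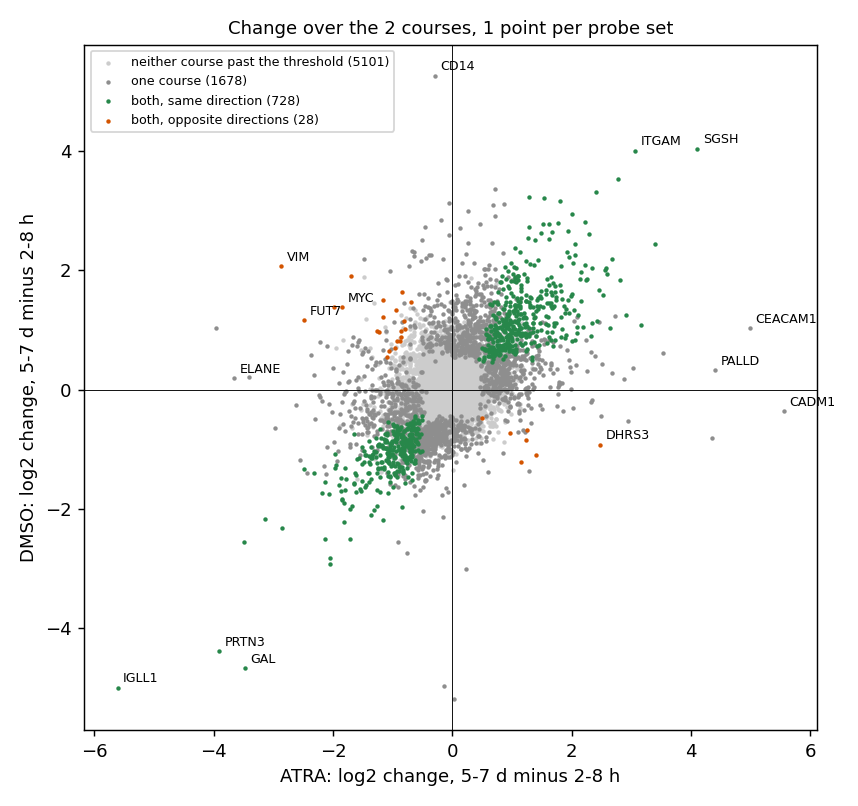
Log2 change of each of 7535 probe sets from 2-8 h to 5-7 d with ATRA on the x axis and with DMSO on the y axis, coloured by which course passed the threshold. Both courses passed in the same direction for 728 probe sets and in opposite directions for 28.

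The courses were then set against each other. Across probe sets, which are not independent replicates, the log2 changes correlated at r = 0.495 and rho = 0.462. In both courses 413 probe sets rose and 315 fell, where 94.5 and 73.7 would be expected of independent lists. In opposite directions 28 passed, where 167 would be expected of independent lists. Time in culture, common to both courses, may add to the agreement and was not tested apart. Whether a change differed between treatments was asked only by the test of the difference, which 236 probe sets passed, 102 with a higher and 134 with a lower change in ATRA. With median centring, which moved the median of all probe sets by 0.113, these counts were 128 and 106, and with quantile normalization 113 and 120. The genes below were picked after their values were seen, because both courses passed in opposite directions. VIM, which fell by 2.87 with ATRA, rose by 2.07 with DMSO and reached 30240 ± 3730 against 572 ± 148, a difference of -4.94 ± 0.49 (adjusted p = 5.42e-06). The fucosyltransferase of selectin ligands FUT7 and the transcription factor NFE2 differed by -3.65 ± 0.53 and -3.61 ± 0.48 (adjusted p = 0.000307 and 0.000126). MYC differed by -3.22 ± 0.34 (adjusted p = 9.16e-06): from 15690 at 0 h it was at 11450 early and 3101 late with ATRA, and at 1696 early and 4527 late with DMSO. CXCR4, the receptor that holds granulocytes in the marrow, differed by -2.67 ± 0.25 (adjusted p = 1.96e-06), and PECAM1, RXRA, LYZ and MYB by -2.47, -2.37, -2.16 and -1.70 (adjusted p = 0.000117, 0.00176, 0.000473 and 0.000758). MYB was under its 0 h level of 9089 in both courses, at 5644 early and 2967 late with ATRA and at 2498 early and 4486 late with DMSO. DHRS3, ITGB7 and CEACAM8 rose with ATRA and fell with DMSO, with differences of 3.40, 2.50 and 2.38 (adjusted p = 4.06e-05, 0.00176 and 0.000146). Further probe sets did not pass for PECAM1 (adjusted p = 0.0823), for RXRA (adjusted p = 0.246) and, in 6 cases, for MYB (adjusted p from 0.0692 to 0.871).

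The group of myeloid transcription factors differed between the courses. Of 24 genes 10 had a lower change in ATRA, 13 when adjusted over the list alone (median difference -1.04, camera adjusted p = 6.91e-10, adjusted p = 0.0114 with an estimated correlation). Cytokines and NF-kB targets were lower in 4 of 16 cases, against 6 lower and 1 higher when adjusted over the list alone (camera adjusted p = 3.16e-05, adjusted p = 0.058 with an estimated correlation). Cytosolic ribosomal proteins had a higher change in ATRA, with 1 of 45 passing and 6 when adjusted over the list alone (median difference 0.47, or 0.19 with quantile normalization, camera adjusted p = 6.91e-10, adjusted p = 0.446 with an estimated correlation). The test of the difference leaned on single arrays: its count was 150, 137 and 155 without the ATRA 2 h, 4 h or 7 d array, 396 without the ATRA 6 d array, and 145, 139 and 147 without the DMSO 4 h, 6 d or 7 d array.

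ATRA and DMSO were next compared at matched times, which asks what distinguishes the treatments. At 2-8 h the monocyte chemokine CCL2 was 14.6-fold higher with ATRA, at 16340 ± 5150 against 991 ± 276 (log2 difference 3.87 ± 0.39, adjusted p = 4.85e-06). The transglutaminase TGM2 was higher, at 1994 ± 1420 against 49.0 ± 22.0 (log2 difference 3.40 ± 0.35, adjusted p = 4.85e-06). Its signal with DMSO lay under the added constant of 119.8 in every window, so no fold is given for it. MYC and the inhibitor of differentiation ID1 were 6.41-fold and 6.38-fold higher (both at adjusted p = 7.05e-07), and G0S2, NFE2, SMOX, SLC2A5, CXCR4 and P2RY2 were higher by 2.77, 2.50, 2.20, 2.13, 1.69 and 1.48 on the log2 scale (adjusted p from 4.85e-06 to 0.00139). ZCCHC24 was lower by a log2 difference of -1.95 ± 0.35 (adjusted p = 0.00415). ITGAM, CD38, MPO and CYP26A1 did not differ past the threshold (adjusted p = 0.602, 0.177, 0.892 and 0.94). Weak or further probe sets did not pass for TGM2 (log2 -0.08, adjusted p = 0.975), CCL2 (adjusted p = 0.0939), ID1 (adjusted p = 0.123) and, in 1 of 3 cases, MYC (adjusted p = 0.246).

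Among groups at 2-8 h, myeloid transcription factors were higher with ATRA in 7 of 24 cases, 11 when adjusted over the list alone (camera adjusted p = 5.01e-07, adjusted p = 0.0146 with an estimated correlation). They included CEBPB, 15250 against 4379 (adjusted p = 0.000119), GFI1 (adjusted p = 0.000701) and CEBPE, 8685 ± 1230 against 3305 ± 617 (adjusted p = 0.0199). Retinoid targets were higher in 4 of 12 cases, 5 when adjusted over the list alone, and chemoattractant receptors in 2 of 9, 5 when adjusted over the list alone (camera adjusted p = 7.66e-05 and 2.67e-05, both at adjusted p = 0.00501 with an estimated correlation). CEBPE was not past the threshold without the ATRA 4 h, ATRA 8 h or DMSO 4 h array (adjusted p = 0.0673, 0.0924 and 0.141). Fitted on the 6 arrays alone, SLC2A5, P2RY2, GFI1, CEBPE and ZCCHC24 did not pass (adjusted p = 0.111, 0.0689, 0.109, 0.0516 and 0.0769). The window gave 92 probe sets, 73 higher and 19 lower. The count was 43, 49, 43 and 54 without the ATRA 4 h, ATRA 8 h, DMSO 4 h or DMSO 8 h array, 199 without the DMSO 2 h array and 24 from the 6 arrays alone.

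At 12-24 h the azurophil granule genes separated the treatments. PRTN3 was 23.6-fold higher with ATRA, at 44730 ± 1300 against 3729 ± 4760 (log2 difference 4.56 ± 0.74, adjusted p = 0.000664). ELANE was 5.85-fold higher, at 41300 ± 11900 against 9951 ± 10200 (adjusted p = 0.00759), and MPO 2.96-fold, at 91590 ± 30900 against 32400 ± 16400 (adjusted p = 0.00243). Of 9 azurophil granule genes 7 were higher with ATRA, 8 when adjusted over the list alone, including AZU1 and DEFA4 by 1.84 and 1.77 on the log2 scale (median 1.60, camera adjusted p = 2.88e-09, adjusted p = 0.0127 with an estimated correlation). Specific granule genes were higher in 3 of 10 cases, 5 when adjusted over the list alone, among them LTF by 1.83 and CEACAM8 by 1.79 (camera adjusted p = 5.04e-06, adjusted p = 0.0127 with an estimated correlation). ELANE did not pass without the DMSO 1 d array (adjusted p = 0.0539), nor did ELANE and MPO when only the 6 arrays were fitted (adjusted p = 0.0841 and 0.0685).

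Other genes higher with ATRA at 12-24 h were TGM2, by 4.37 ± 0.35 on the log2 scale (adjusted p = 1.76e-07), the prostaglandin synthase PTGES, by 3.78, the fructose carrier SLC2A5, G0S2, SMOX, CCL2, FBP1, DHRS3 and CEACAM6, by log2 differences from 2.29 to 3.70, and CD38, at 1408 ± 129 against 36.7 ± 20.8 (adjusted p = 1.19e-05). VIM and IL1RN were lower, by log2 differences of -3.19 and -2.19 (adjusted p = 9.82e-06 and 0.000513). MYC was 4.07-fold higher (adjusted p = 1.71e-05), and 8 of 16 MYC targets and ribosome biogenesis genes were higher, 12 when adjusted over the list alone, with NME1 up by 1.72 and SRM by 1.51 (camera adjusted p = 3.44e-12, adjusted p = 0.0452 with an estimated correlation). Retinoid targets were higher in 4 of 12 cases, 4 when adjusted over the list alone (camera adjusted p = 9.02e-05, adjusted p = 0.00989 with an estimated correlation and 0.073 with the 60th percentile filter). Mitosis genes were lower in 7 of 32 cases, 13 when adjusted over the list alone, among them CCNA2, CENPE and CDC25B (camera adjusted p = 8.09e-08, adjusted p = 0.268 with an estimated correlation). ITGAM did not pass (adjusted p = 0.112), but was lower with ATRA without the DMSO 12 h array (log2 -1.94, adjusted p = 0.00403). Further probe sets did not pass for MYC (adjusted p = 0.615), CCL2 (adjusted p = 0.0505), CCNA2 (adjusted p = 0.0664), IL1RN (adjusted p = 0.909) and SRM (adjusted p = 0.967). The window gave 560 probe sets, 316 higher and 244 lower, and 359 higher and 165 lower with median centring. The count was 282, 274, 320 and 320 without the ATRA 12 h, ATRA 18 h, DMSO 18 h or DMSO 1 d array, and 262 from the 6 arrays alone.

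At 2-4 d VIM was 34.7-fold lower with ATRA, at 876 ± 463 against 32470 ± 4730 (log2 difference -5.12 ± 0.35, adjusted p = 1.56e-08). The calcium-binding alarmins S100A9 and S100A8 were lower by log2 differences of -3.38 and -1.71 (adjusted p = 1.07e-05 and 0.000981), CD14 by -3.32 (adjusted p = 0.000842), lysozyme, encoded by LYZ, by -2.94 (adjusted p = 5.96e-08), and PLXNC1, PECAM1, SERPINA1, TNFRSF10B and TLR2 by -2.46, -2.31, -2.16, -1.51 and -1.36 (adjusted p from 1.94e-06 to 0.00552). TGM2 was higher with ATRA, at 4398 ± 932 against 48.9 ± 35.6 (log2 difference 4.74 ± 0.35, adjusted p = 3.64e-08), SLC2A5 was 17.7-fold higher (adjusted p = 8.14e-08), and CEACAM1, PRTN3, DHRS3 and SMOX were higher by 3.95, 3.92, 3.48 and 3.44 on the log2 scale. CD38 was higher by 2.27 (adjusted p = 0.000578). ITGAM, MPO and MYC did not pass (adjusted p = 0.195, 0.154 and 0.225). Of 13 S100 and annexin genes 5 were lower, 7 when adjusted over the list alone (camera adjusted p = 0.00023, adjusted p = 0.112 with an estimated correlation). Retinoid targets were higher in 3 of 12 cases, 3 when adjusted over the list alone (camera adjusted p = 0.00144, adjusted p = 0.0418 with an estimated correlation and 0.181 with the 60th percentile filter). A weak further probe set of TGM2 did not differ (log2 0.17, adjusted p = 0.855). The window gave 450 probe sets, 211 higher and 239 lower, and 260 and 271 without the ATRA 2 d or DMSO 4 d array, and 127 from the 6 arrays alone.

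At 5-7 d CADM1 was higher with ATRA, at 9517 ± 3520 against 52.0 ± 20.3 (log2 difference 5.74 ± 0.50, adjusted p = 1.54e-07), and so was DHRS3, by 4.77. With DMSO both signals lay under the added constant, so no fold is given. PALLD was 39.4-fold higher, SLC2A5 33.4-fold and CEACAM1 23.7-fold (adjusted p of these 3 and DHRS3 from 1.41e-09 to 2.88e-07). FBP1, ITGB7, CD38, CEACAM8 and NPC2 were also higher (adjusted p from 6.13e-07 to 0.000422). VIM was 44.4-fold lower (adjusted p = 2.16e-09), CD14 was at 1331 ± 98.5 against 23970 ± 3570 (adjusted p = 6.56e-05), and ELANE at 3797 ± 1600 against 50720 ± 11700 (adjusted p = 0.000112), so that its order was opposite to that of 12-24 h. SERPINA1, AHNAK, CA2, S100A9, FCN1, LIPA, CTSG and RXRA were lower by log2 differences of -3.12, -2.77, -2.71, -2.58, -2.24, -2.17, -1.67 and -1.65 (adjusted p from 1.29e-07 to 0.00186). ITGAM, CYBB, MPO and MYC did not pass (adjusted p = 0.75, 0.948, 0.843 and 0.181), while a further probe set of MYC was lower with ATRA (log2 -1.34, adjusted p = 0.0248). Cytosolic ribosomal proteins were higher in 6 of 45 cases, 13 when adjusted over the list alone (median 0.39, camera adjusted p = 2.91e-09, adjusted p = 0.519 with an estimated correlation). Of 28 lysosome genes 7 were higher and 2 lower, 8 and 3 when adjusted over the list alone, and of 24 myeloid transcription factors 6 were lower and 1 higher, 11 and 1 when adjusted over the list alone (both at camera adjusted p = 0.00813, with adjusted p = 0.466 and 0.375 with an estimated correlation). The window gave 714 probe sets, 322 higher and 392 lower, and 362 higher and 338 lower with median centring. The count was 423, 410, 367 and 470 without the ATRA 5 d, ATRA 7 d, DMSO 6 d or DMSO 7 d array, and 377 from the 6 arrays alone.

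Paired over all 12 times, TGM2 was higher with ATRA at 12 of 12 times, at a mean of 3222 ± 1230 against 48.03 ± 20.8 (SD, n = 12 each), a log2 difference of 4.19 ± 0.20 of signal plus the constant (adjusted p = 6.82e-09). SLC2A5, PTGES, DHRS3, SMOX, G0S2, FBP1 and CCL2 were higher at 12 of 12 times, by 3.76, 3.08, 3.07, 2.93, 2.79, 2.57 and 2.42 on the log2 scale (adjusted p from 5.56e-08 to 0.000409), and CD38 at 11 of 12 times, by 2.41 (adjusted p = 0.000112). CEBPE was higher at 10 of 12 times, by 0.78 (adjusted p = 0.0125). VIM was 11.9-fold lower at 12 of 12 times (adjusted p = 0.000554). Also lower were PLEC, 2.67-fold, at 11 of 12 times (adjusted p = 0.0011), and the ganglioside synthase ST3GAL5 and the metallothionein MT1X at 12 of 12 times, by log2 differences of -1.28 and -1.19 (adjusted p = 0.000939 and 0.000139). Further probe sets of PLEC and TGM2 did not pass (adjusted p = 0.143 and 0.441). Retinoid targets were higher in 5 of 12 cases, 5 when adjusted over the list alone (camera adjusted p = 0.00111, adjusted p = 0.0479 with an estimated correlation and 0.158 with the 60th percentile filter), and so were 5 of 16 MYC targets and ribosome biogenesis genes, 11 when adjusted over the list alone (camera adjusted p = 5.46e-05, adjusted p = 0.638 with an estimated correlation). Past the threshold were 1104 probe sets, 504 higher and 600 lower, and 121 of them differed at least 2-fold. With median centring the counts were 519 higher and 515 lower.

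**Figure D3:**
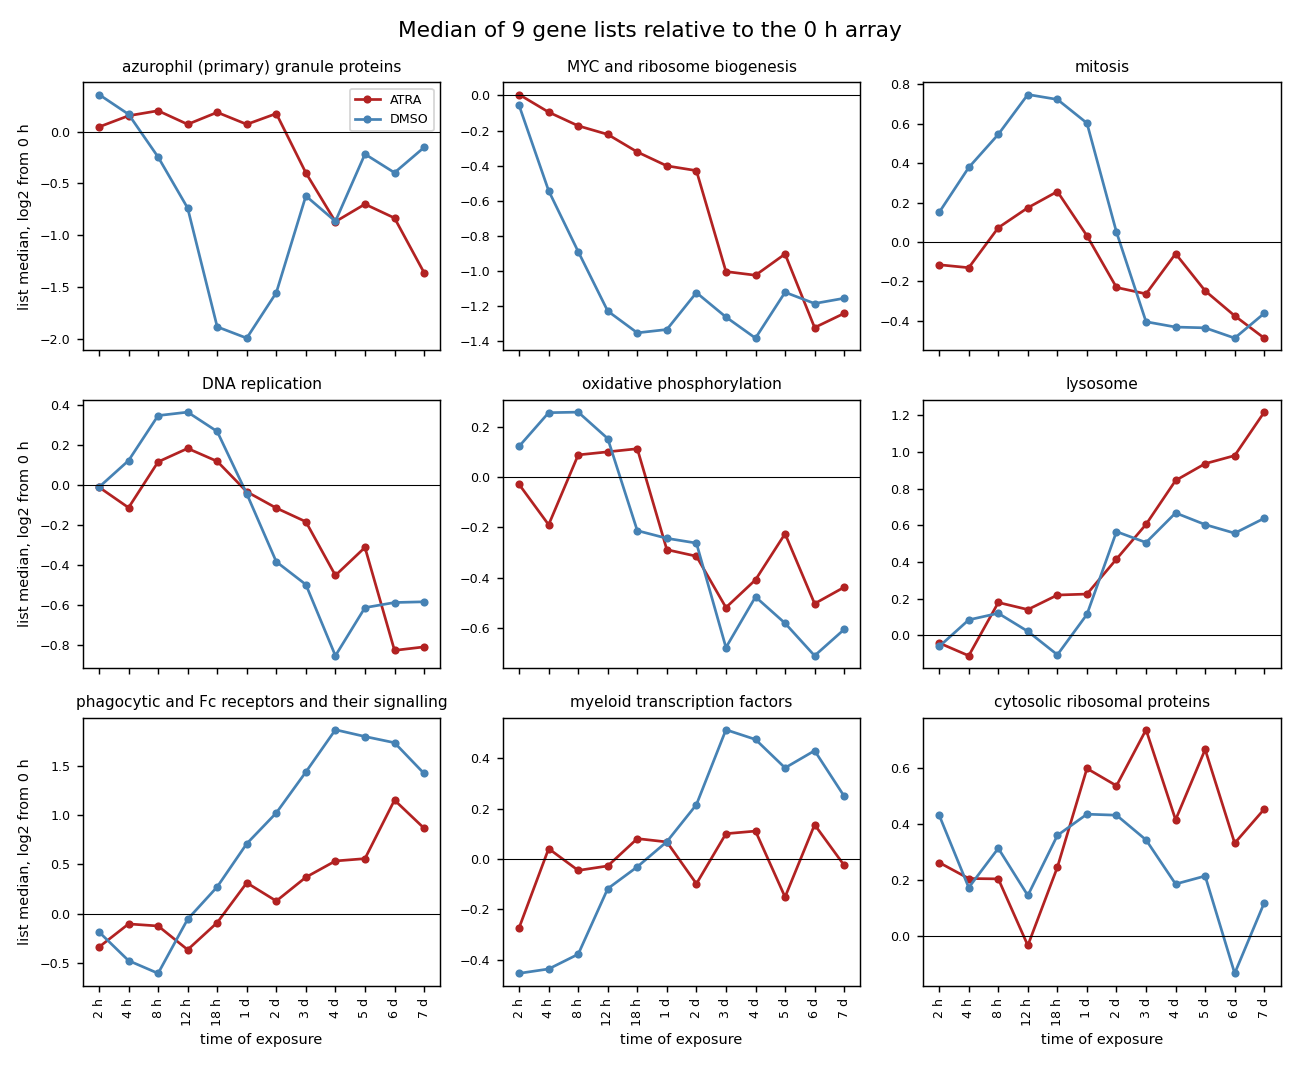
Median log2 difference from the 0 h array over the members of 9 gene lists, against time of exposure, with ATRA in red and DMSO in blue. The azurophil granule median of the DMSO course was -1.88 at 18 h, -1.99 at 1 d and -0.15 at 7 d.

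The early windows were also set against the undifferentiated cells. With 1 array at 0 h, that array was assumed to vary as the others did. After 2-8 h of ATRA 3 probe sets passed, all up: TGM2, from 29.9 to 1994 ± 1420 (log2 3.56 ± 0.50, adjusted p = 0.00123), SMOX, a spermine oxidase, 9.77-fold (adjusted p = 0.000186), and ID1, 5.86-fold (adjusted p = 0.000591). Further probe sets did not pass for TGM2 (log2 -0.13, adjusted p = 0.998), SMOX (adjusted p = 0.127) or ID1 (adjusted p = 0.41 and 0.998). CD38 and MYC did not pass (log2 1.54 and -0.47, both at adjusted p = 0.997). Retinoid targets rose as a group, with 1 of 12 passing and 4 when adjusted over the list alone (camera adjusted p = 0.000844, adjusted p = 0.0191 with an estimated correlation). The count of 3 became 6 without the ATRA 2 h array, and 0 in limma from the 4 arrays alone, where 452 had an unadjusted p under 0.05.

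After 2-8 h of DMSO 13 probe sets passed and all of them fell. MYC went from 15690 to 1696 ± 425 and fell by 3.15 ± 0.34 (adjusted p = 2.69e-05), GPR183 fell by 2.13 (adjusted p = 0.0207), CEBPD and GFI1 changed by -2.06 and -1.86 (both at adjusted p = 0.0285), and MYB by -1.82 (adjusted p = 0.00199). Without the DMSO 4 h array GPR183, CEBPD and GFI1 did not pass (adjusted p = 0.0833, 0.134 and 0.0833), and CEBPD did not pass with quantile normalization (adjusted p = 0.0742). CEBPD and GFI1 were at adjusted p = 0.0513 without the filter. A further probe set of MYC did not pass, nor did 7 of MYB, 1 of which had the opposite sign (log2 0.56, adjusted p = 1). Myeloid transcription factors fell in 3 of 24 cases, 8 when adjusted over the list alone (camera adjusted p = 1.32e-06, adjusted p = 0.067 with an estimated correlation). The count was 48 without the DMSO 2 h array, 5 without the DMSO 4 h array, 8 without the ATRA 4 h, ATRA 12 h, ATRA 5 d or DMSO 6 d array, and 0 in limma from the 4 arrays alone, where 412 had an unadjusted p under 0.05.

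By 5-7 d, 686 probe sets differed from 0 h with ATRA, 347 up and 339 down, and 751 with DMSO, 388 up and 363 down. With median centring the counts were 295 up and 328 down with ATRA and 305 up and 406 down with DMSO, where the median of all probe sets moved by -0.103. With quantile normalization they were 361 up and 383 down with DMSO. With ATRA 14 of 28 lysosome genes rose and 2 fell, 18 and 2 when adjusted over the list alone (camera adjusted p = 4.31e-10, adjusted p = 0.0427 with an estimated correlation), and 8 of 16 MYC targets and ribosome biogenesis genes fell, 11 when adjusted over the list alone (camera adjusted p = 3.39e-09, adjusted p = 0.137 with an estimated correlation). With DMSO 6 of 11 phagocytic and Fc receptor genes rose, 8 when adjusted over the list alone, and 7 of 16 MYC targets and ribosome biogenesis genes fell, 11 when adjusted over the list alone (camera adjusted p = 3e-05 and 2.08e-08, both at adjusted p = 0.237 with an estimated correlation). The ATRA count was 385 without the ATRA 7 d array and 9 from the 4 arrays alone, and the DMSO count was 431 without the DMSO 6 d array and 392 from the 4 arrays alone.

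The distance between whole profiles was followed over time. The root mean square log2 difference between the ATRA and DMSO arrays of the same time was 0.583 ± 0.0539 at 2-8 h, 0.668 ± 0.0665 at 12-24 h, 0.695 ± 0.0207 at 2-4 d and 0.746 ± 0.0666 at 5-7 d (SD, n = 3). Between arrays of 1 treatment within a window, which differ in time, the same measure averaged 0.501 with ATRA and 0.538 with DMSO at 2-8 h, and 0.626 and 0.482 at 5-7 d. The distance of 0.521 between treatments at 2 h was within the range of these early distances. An exact permutation test of 5-7 d against 2-4 d gave p = 0.3, and 1 of 2-8 h against 2-4 d gave p = 0.1, the lowest that 3 times on each side allow, so this test cannot settle whether windows differed. Over the 12 times it rose with the logarithm of time (r = 0.835, permutation p = 7e-04, rho = 0.755, permutation p = 0.00622, adjusted p = 7e-04 and 0.00622 over 3 relations), and without the 2 h and 4 h arrays r was 0.716. The distance from 0 h rose with ATRA (r = 0.882, permutation p = 0.00031, rho = 0.909, permutation p = 1e-04, adjusted p = 0.000465 and 0.000195) and with DMSO (r = 0.951, permutation p = 3e-05, rho = 0.902, permutation p = 0.00013, adjusted p = 9e-05 and 0.000195). Without the 2 h and 4 h arrays r was 0.971 with ATRA and 0.901 with DMSO. Neighbouring times of a course are not independent samples, which these p-values do not take into account.

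**Figure D4:**
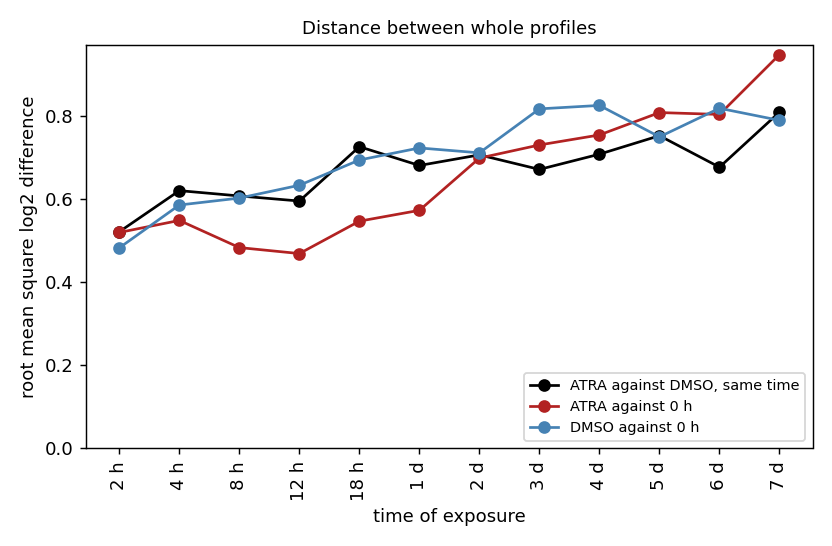
Root mean square log2 difference over 7535 probe sets against time of exposure, between ATRA and DMSO arrays of the same time in black and between each treated array and the 0 h array in colour. The distance between treatments went from 0.521 at 2 h to 0.809 at 7 d.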

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

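Some tests were chosen only after the result was seen. They were that on single arrays for azurophil granule genes, quantile normalization for ribosomal proteins, and that on the 0 h array. The random lists for the azurophil granule genes tested a change within DMSO whose contrast was also chosen only after the result was seen. The change over the course differed between ATRA and DMSO, by a test of the difference itself, for 236 probe sets. Values below are the ATRA change minus the DMSO change on the log2 scale. Groups of 3 arrays, and of 12, were not searched for single arrays far from the others.

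Of the 236 probe sets 134 had a lower change in ATRA and 102 a higher one, and with median centring the counts were 106 and 128. Of the 100 genes named, which were picked in part for large or opposite changes, 41 differed in this way, 32 lower and 9 higher, so this share does not speak for all genes. The lower ones began with CD14 at -5.56, VIM at -4.94, ELANE at -3.84, FUT7 at -3.65, NFE2 at -3.61, AHNAK at -3.61, MYC at -3.22, CCL2 at -3.20, IL1RN at -3.05 and SERPINA1 at -3.02. ID1 was at -2.95, TNFRSF10B at -2.88, PLXNC1 at -2.74, CA2 at -2.69, CXCR4 at -2.67, S100A9 at -2.57, PECAM1 at -2.47, CDC42EP3 at -2.41, RXRA at -2.37, ZBTB16 at -2.36, LILRB3 at -2.24, FCN1 at -2.17, LYZ at -2.16 and IL1B at -2.15. PLEC was at -1.98, CTSG at -1.81, MYB at -1.70, TLR2 at -1.67, P2RY2 at -1.66, LIPA at -1.64, GFI1 at -1.49 and CEBPD at -1.45. The change was higher in ATRA for CADM1 at 5.92, PALLD at 4.08, CEACAM1 at 3.96, DHRS3 at 3.40, SLC2A5 at 2.93, ITGB7 at 2.50, CEACAM8 at 2.38, NPC2 at 2.06 and DEFA4 at 1.56. A lower change does not mean a lower late level. CCL2 was higher with ATRA by 3.87 on the log2 scale at 2-8 h and by 2.42 over the 12 matched times. MYC, ID1, GFI1 and CEBPD were higher with ATRA by 2.68, 2.67, 1.63 and 1.39 at 2-8 h, so in these probe sets most of their differences lay in the early window. At 5-7 d MYC did not differ past the threshold (log2 -0.54, adjusted p = 0.181 in limma), though a further probe set was lower with ATRA (log2 -1.34, adjusted p = 0.0248). MYB, NFE2, CXCR4 and P2RY2 were also higher with ATRA at 2-8 h, so their differences come at least in part from the early window.

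Among gene lists the median difference was -1.06 for specific granule proteins, -1.04 for myeloid transcription factors, -0.776 for cytokines and NF-kB targets, -0.556 for chemoattractant receptors, -0.491 for MYC targets and ribosome biogenesis, -0.481 for phagocytic and Fc receptors, -0.309 for apoptosis regulators and -0.197 for leukocyte adhesion molecules. It was 0.486 for mitosis, 0.468 for cytosolic ribosomal proteins, 0.428 for oxidative phosphorylation and 0.265 for the lysosome. With an estimated correlation only the myeloid transcription factors passed, at adjusted p = 0.0114. That list was already higher with ATRA at 2-8 h, so its difference comes at least in part from the early window. Several of these calls were lost without 1 array. Without the DMSO 8 h array the adjusted p was 0.156 for specific granule proteins, 0.264 for MYC targets and ribosome biogenesis, 0.117 for phagocytic receptors and 0.11 for adhesion molecules. Without the ATRA 6 d array it was 0.0859, 0.0614, 0.0868 and 0.082 for the same lists and 0.0539 for apoptosis regulators. Without the filter the adjusted p was 0.187 for specific granule proteins, at a median of -0.37, 0.0888 for apoptosis regulators and 0.0606 for adhesion molecules. With the 60th percentile filter it was 0.262 for specific granule proteins, 0.0709 for apoptosis regulators and 0.202 for phagocytic receptors, with a smaller constant 0.0514 for phagocytic receptors, and with the mean of all probe sets 0.0738 for apoptosis regulators. Further losses were those of specific granule proteins without the DMSO 5 d array (0.0619), of phagocytic receptors without the ATRA 8 h, ATRA 5 d or DMSO 5 d array (0.0901, 0.0672 and 0.0701), and of apoptosis regulators without the ATRA 8 h, ATRA 5 d, DMSO 2 h or DMSO 5 d array (0.0564, 0.0522, 0.0505 and 0.0651).

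The test of the difference was repeated with the treatments exchanged within pairs of the same time. Of 32 such splits 3 gave as many probe sets as the real 236, the highest of the others being 475, so chance is not excluded for that count by this test. The 8 splits that kept the 3 late times together gave from 107 to 475, and the other 24 gave at most 18. The former carry the late difference between treatments, so this exchange does not separate the count of 236 from that difference.

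The azurophil granule genes had a median change of -1.53 from 2-8 h to 12-24 h of DMSO. Of 10000 random lists of like brightness, 0 had a median as low (central range -0.327 to 0.262, median -0.0323). This argues against a shift common to genes of that brightness. The lists were drawn gene by gene without the azurophil granule genes, which may move together, so the value of 0 overstates how rare such a list is. The change was not refitted with other scaling, so some effect of scaling is not excluded. All 3 DMSO arrays of 12-24 h correlated best with an array of a neighbouring time, which argues against arrays out of place. With any 1 array left out the highest camera adjusted p of the list between treatments in that window was 1.49e-07, at the preset correlation. This argues against a single array for the difference between treatments there. The change within DMSO was not refitted with arrays left out. As far as these tests reach, a loss of azurophil transcripts in DMSO-treated cells may be biological, which stays a hypothesis found and tested on the same data. Whether it passed is open, since the later rise of the list was at adjusted p = 0.101 with an estimated correlation and PRTN3 and DEFA4 did not rise, and culture events common to 3 arrays were not tested.

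The change of ribosomal protein genes differed between the courses by a median of 0.47. Of 45 genes 1 passed the test of the difference, and the list did not pass camera with an estimated correlation. With quantile normalization the difference was 0.191, so array scaling could account for part of it, and this explanation stays open. Of 10000 random lists of like brightness 0 had a median as high (central range -0.0818 to 0.247), so other genes of like brightness did not shift as far. These lists were drawn gene by gene without the ribosomal protein genes, which may move together. As quantile normalization also took away much of the difference, a shift tied to brightness is not excluded. A biological difference between the agents stays open and was not tested apart from scaling.

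The early falls with DMSO rest on 1 array at 0 h. Of the 13 probe sets that fell, 11 were lower with DMSO than with ATRA at 2-8 h, a comparison that leaves that array out. The 13 were picked through low values in the same DMSO arrays, however, so a lean to lower values with DMSO was built in. MYC and GATA2 each had several of these probe sets, so the 13 are fewer genes. The value of 11 thus cannot settle whether an odd 0 h array was the source. The ATRA arrays of 2-8 h were below the 0 h array too in all 13, by a median of -0.62 against -2.07 with DMSO, each at adjusted p = 0.997, so a high 0 h array could add to the falls and stays open in part. An effect of DMSO within the first hours was not tested apart from that selection and remains a hypothesis.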

How the results depend on the processing

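The alternative without the ATRA 7 d and DMSO 3 d arrays was chosen only after the result was seen. Counts of probe sets past the threshold and profile measures stayed within 1.5 times of their value, or on their side of the test, in 140 of 156 other settings and in 312 of 344 fits with 1 array left out. For comparisons of windows, most fits with 1 array left out dropped an array outside the windows compared. That changes only the shared estimate of the spread, so the value of 312 overstates how little single arrays matter.

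With 1 array left out the count ran from 966 to 1507 for the ATRA course, 1162 to 1765 for the DMSO course, 137 to 396 for the difference of the changes, 43 to 199 at 2-8 h, 274 to 627 at 12-24 h, 260 to 492 at 2-4 d, 367 to 906 at 5-7 d and 819 to 1148 over the 12 times. Against 0 h it ran from 3 to 6 and 385 to 760 with ATRA, and from 5 to 48 and 431 to 806 with DMSO, early and late.

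The 13 early falls with DMSO became 7 with quantile normalization, 6 without the filter and 20 with the 60th percentile filter, and the 3 early rises with ATRA became 5 with trend and robust. The cause was not tested. From the arrays of the comparison alone, which leave fewer samples to estimate the spread, the count was 24 at 2-8 h, 262 at 12-24 h, 127 at 2-4 d and 377 at 5-7 d. Against 0 h it was 0 and 9 with ATRA and 0 and 392 with DMSO, early and late, where limma gave 452 and 412 early probe sets at an unadjusted p under 0.05. Without the ATRA 7 d and DMSO 3 d arrays it was 949 for the ATRA course, 145 for the difference, 413 at 5-7 d and 408 for ATRA at 5-7 d against 0 h.

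The sign changed in 5 results for which the main or the alternative test passed the threshold. Sign changes where neither passed were not counted, such as that of a weak probe set of CYP26A1 in the DMSO course (log2 -0.47 against 0.45). The median of the ribosomal proteins against 0 h became -0.0317 for ATRA at 2-8 h (adjusted p = 0.714), and with DMSO at 2-8 h the test turned down at a median of 0.00199 (adjusted p = 0.794), both with quantile normalization. A weak further probe set of TGM2 gave -0.0771 at 2-8 h and -0.13 against 0 h, and 1 of MYB gave 0.56 with DMSO against 0 h. None of the 5 passed the threshold under the alternative, and the cause was not tested.

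Named genes stayed on their side of the threshold in 5078 fits with 1 array left out and lost it in 11, and in other settings these counts were 2044 and 21. Further probe sets did so in 57 and 33 cases, with 2 that passed in place of a main probe set that did not. List calls stayed in 2160 and were lost in 55 fits with 1 array left out, and in other settings stayed in 736 and were lost in 152. For named genes and lists too, most fits with 1 array left out dropped an array outside the windows compared. Staying was therefore likely in advance, the more so as named genes were picked in part for large changes. Signals near the constant of 119.8 carry little information on folds.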

Other observations

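The contrasts of 12-24 h with 2-8 h and with 5-7 d, within the DMSO and within the ATRA course, were chosen only after the result was seen, and they are the basis of the first 3 paragraphs. From 2-8 h to 12-24 h of DMSO 296 probe sets passed the threshold in limma, 161 up and 135 down. Azurophil granule genes fell in 7 of 9 cases (median -1.53, camera adjusted p = 1.22e-09, adjusted p = 0.0186 with an estimated correlation), PRTN3 by a log2 change of -4.39 ± 0.74, ELANE by -2.68 ± 0.56, CTSG by -2.48 ± 0.32 and MPO by -1.53 ± 0.29 (adjusted p = 0.00216, 0.0101, 0.000645 and 0.00507). Genes of the ER stress and amino acid response fell in 5 of 17 cases (camera adjusted p = 1.08e-08, adjusted p = 0.0186 with an estimated correlation), and specific granule genes in 4 of 10 (camera adjusted p = 9.44e-05, adjusted p = 0.0301 with an estimated correlation). Eosinophil, basophil and mast cell markers fell in 2 of 6 cases (median -1.01, camera adjusted p = 0.000522, adjusted p = 0.0301 with an estimated correlation). Apoptosis regulators rose as a list, with 1 of 21 genes passing (median 0.42, camera adjusted p = 0.000449, adjusted p = 0.0218 with an estimated correlation). In the ATRA course 1 probe set passed between the same windows. Retinoid targets rose there as a list, with 0 of 12 genes passing (median 0.45, camera adjusted p = 0.000634, adjusted p = 0.0165 with an estimated correlation). The ER stress and amino acid response list fell with ATRA too (median -0.31, camera adjusted p = 0.000634), but did not pass with an estimated correlation (adjusted p = 0.275).

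From 12-24 h to 5-7 d of DMSO 712 probe sets passed, 343 up and 369 down. Azurophil granule genes rose in 6 of 9 cases (median 1.56, camera adjusted p = 0.000117, adjusted p = 0.101 with an estimated correlation), among them ELANE by 2.86, CTSG by 1.98 and MPO by 1.64 (adjusted p = 0.00253, 0.000549 and 0.0012). PRTN3 and DEFA4 did not pass (log2 0.00 and -0.59, adjusted p = 0.999 and 0.211). SERPINB1 was among the genes that rose, by 1.65, but had not fallen from 2-8 h to 12-24 h (log2 0.37, adjusted p = 0.614 in limma). Specific granule genes rose in 5 of 10 cases (camera adjusted p = 6.9e-05, adjusted p = 0.0494 with an estimated correlation).

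Mitosis genes of the DMSO course were above the 0 h array by a median of 0.75 at 12 h, 0.72 at 18 h and 0.60 at 1 d, and were at -0.36 at 7 d. In the ATRA course the median was at most 0.26, at 18 h, and -0.49 at 7 d. From 2-8 h to 12-24 h of DMSO 1 of 32 mitosis genes rose (median 0.40, camera adjusted p = 0.000511, adjusted p = 0.359 with an estimated correlation), so an early rise is not established. From 12-24 h to 5-7 d of DMSO 28 of 32 mitosis genes fell (median -1.15, camera adjusted p = 3.17e-27, adjusted p = 0.0189 with an estimated correlation), with TOP2A and CCNB1 both at -1.43 and CDK1 at -1.26. DNA replication genes fell in 21 of 37 cases (camera adjusted p = 6.15e-15, adjusted p = 0.128 with an estimated correlation). Between the same windows of ATRA 1115 probe sets passed, 541 up and 574 down, mitosis genes fell in 10 of 32 cases and DNA replication genes in 18 of 37 (median -0.55 and -0.73, camera adjusted p = 1.1e-07 and 1.58e-11, both at adjusted p = 0.256 with an estimated correlation).

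The arrays of each comparison were also split in other ways into groups of the same sizes. With 10 splits for 6 arrays the splits are too few for a share under 0.05. Each other split also mixed arrays of both windows, or of both treatments, within a group. Real differences then counted as spread, so low counts were likely in advance and say nothing on chance. In the ATRA course the real split gave 1462 probe sets and the highest of the others 7, and in the DMSO course 1728 and 1. Between treatments the real split gave 92 at 2-8 h, 560 at 12-24 h, 450 at 2-4 d and 714 at 5-7 d, and the highest of the others 0, 0, 1 and 1. Over the 12 times, treatments were exchanged within pairs in 100 of the 2048 possible ways. Only the real one gave as many as 1104, with 57 as the highest of the others. That would count against chance only if pairs were exchangeable. The exchange takes the times as independent, which neighbouring times of 1 course are not, so chance is not excluded. Any constant difference between the courses, of whatever origin, would give such a count.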
